A study of Homo sapiens with 2 samples.

How the data were processed

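Total RNA from 2 cultures of the Hodgkin lymphoma cell line L-540, 1 left untreated and 1 treated with vorinostat, was labelled with biotin and hybridised to 1 Affymetrix HG_U133A array each, per the labels' protocols. The values used were the intensity values per probe set that the authors deposited, made with MAS5 per the submitters' processing notes; the MAS5 version, the scaling target and the detection calls were not given in the sources used here. MAS5 reduces the probes of a probe set to 1 signal on a linear scale and scales each array by a single factor. On the deposited values all signals were above 0, and the mean signal after trimming 2% at each end was 500.2 on both arrays, so the scaling was kept as deposited.

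Of 22283 probe sets, 68 control probe sets were used for quality values alone, which left 22215. Gene symbols came from the annotation table of the array platform: 19065 probe sets carried 1 symbol (11963 genes), 1043 carried several and 2107 were not in the table and stay unnamed here. Entrez identifiers of 19053 probe sets were found in a RefSeq gene table of human assembly GRCh38.p14, which changed 0 symbols and was used for names and for which genes neighbour each other. No gene was named from a probe set with several symbols; 717 of those were measured, with 24 at least 2-fold higher and 26 lower, and 1032 unnamed ones were measured, with 27 higher and 45 lower.

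The floor was the 40th percentile of all non-control signals pooled over both arrays, 68.9 signal units, above the highest signal of the 27 B. subtilis poly-A control probe sets (43.1). Signals under the floor were set to it before taking log2. A probe set at the floor on both arrays was not measured, and a probe set at the floor on 1 array gave a bound, written as at least N-fold. Each gene was represented by its probe set with the highest mean log2 signal. This left 8277 measured genes, 7373 of them above the floor on both arrays, 320 at the floor in the untreated and 584 in the treated array. Ratios are vorinostat over untreated. The median log2 ratio was -0.04 with an SD over genes of 0.59, and log2 signals of genes above the floor on both arrays had a Pearson correlation of 0.943 across genes, which are not independent replicates.

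With 1 array per group no test was run and no p-value is given; genes at least 2-fold apart were counted as a rule of size. Each of 38 gene lists was summarised by the median log2 ratio of its measured members, genes at the floor entering at their bound, and placed among 10000 random lists of the same size drawn from measured genes in 20 bins of mean signal level. Lists needed at least 5 measured members. The lists covered responders to histone deacetylase inhibitors, the deacetylases, histones, chromatin modifiers, cell cycle stages, Hodgkin and lymphoid cell identity, cytokine, NF-kB and interferon signalling, antigen presentation, cell death, p53, DNA repair, drug handling, stress responses, metabolism, protein synthesis and turnover, lysosomes, the cytoskeleton, neuronal and cancer-testis genes, and markers of other cell types. Some genes sit in several lists; the lists of NF-kB targets and of Hodgkin cell genes shared 2 measured members.

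The genes named were fixed by a rule: the 12 highest and 12 lowest ratios among genes above the floor on both arrays whose measured probe sets all went the same way; the 5 brightest genes in either direction that were at the floor on the other array; in each list up to 4 members with the largest ratios; and a set of genes of interest, such as CDKN1A, TNFRSF8 and MYC, whatever their values. The groups, the floor, the lists, the naming rule and all alternatives but 1 were set before the data were examined. The alternatives were scaling to equal medians, quantile normalization, loess of the ratio on signal level, floors at the 25th percentile, at the 60th percentile or at the highest poly-A control, an offset of 16 signal units in place of a floor, the median over a gene's probe sets, leaving out probe sets whose suffix marks shared sequence, thresholds of 1.5-fold and 3-fold, 5 bins of level, and the mean in place of the median. Random lists matched on level and on the number of protein-coding neighbours within 1 Mb on each side were added after seeing the data.

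The steps were tested on simulated data for this comparison, with noise of SD 0.25 on 7981 genes. Of the changed genes, 100 of 100 set 4-fold apart and 94 of 100 set 3-fold apart were counted as at least 2-fold. Of 7781 unchanged genes, 38 were counted so too. The noise SD was assumed and not estimated from these arrays, so this count gives no error rate for the genes counted here. The changed genes were drawn from those with a probe set more than 2 log2 units above the floor, and the noise was equal at all signal levels. Recovery of dimmer genes was therefore not tested. Of 100 lists with no shift 6 fell outside the middle 95% of random lists, and 20 of 20 lists shifted by 0.4 were found. The simulated noise was independent between genes, so lists whose genes vary together were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.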

Results

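Gene expression was measured in L-540, an established cell line from Hodgkin lymphoma that is usually described as being of T-cell lineage, in cells left untreated and in cells treated with vorinostat, a hydroxamate that inhibits histone deacetylases. Each group held 1 Affymetrix HG_U133A array, so there were no replicates and the differences below had no replicate check. The labels gave neither the dose nor the time of treatment. Each array reported a MAS5 signal, a linear intensity, for 22283 probe sets. The trimmed mean signal was 500.2 on both arrays. The median signal was 126 on the untreated array and 115 on the treated array, and 61.2% and 58.8% of the non-control probe sets lay above the floor of 68.9 signal units. The 18 hybridisation spike-in probe sets had a mean log2 ratio of 0.06 (SD 0.17 over probe sets). The 3' to 5' signal ratio was 0.856 and 0.850 for the GAPDH control probe sets and 1.06 and 1.24 for the ACTB ones, untreated and treated.

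The comparison of the treated with the untreated array addressed how vorinostat altered the expression profile of Hodgkin lymphoma cells. Of 56 measured genes in the lists for Hodgkin, B and T cells, 17 were at least 2-fold lower in the treated array, 0 were at least 2-fold higher and 39 lay within 2-fold. Among the lower ones TNFRSF8, which encodes the Hodgkin cell antigen CD30, was 3.34-fold lower, the T-cell receptor chain gene CD247 was 4.74-fold lower and the immunoglobulin mu gene IGHM was 7.11-fold lower. The death receptor gene FAS was 5.02-fold lower, and STAT6, which carries interleukin-4 signals, was 2.66-fold lower. Higher in the treated array were DHRS2, a dehydrogenase gene known to respond to histone deacetylase inhibitors (3.20-fold), the linker histone gene H1-10 (2.65-fold), the lysosomal cholesterol transporter gene NPC1 (2.46-fold) and the zinc exporter gene SLC30A1 (2.39-fold). Of 8277 measured genes, 312 (3.77%) were at least 2-fold higher and 424 (5.12%) at least 2-fold lower in the treated array, and 91.1% lay within 2-fold. Of these calls, 42.4% were higher, against 47.6% after quantile normalization, 46.7% without shared-sequence probe sets and 39.98% with the offset. At the 1.5-fold threshold 1051 genes were higher and 1283 lower, and at the 3-fold threshold 45 and 77.

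**Figure D1:**
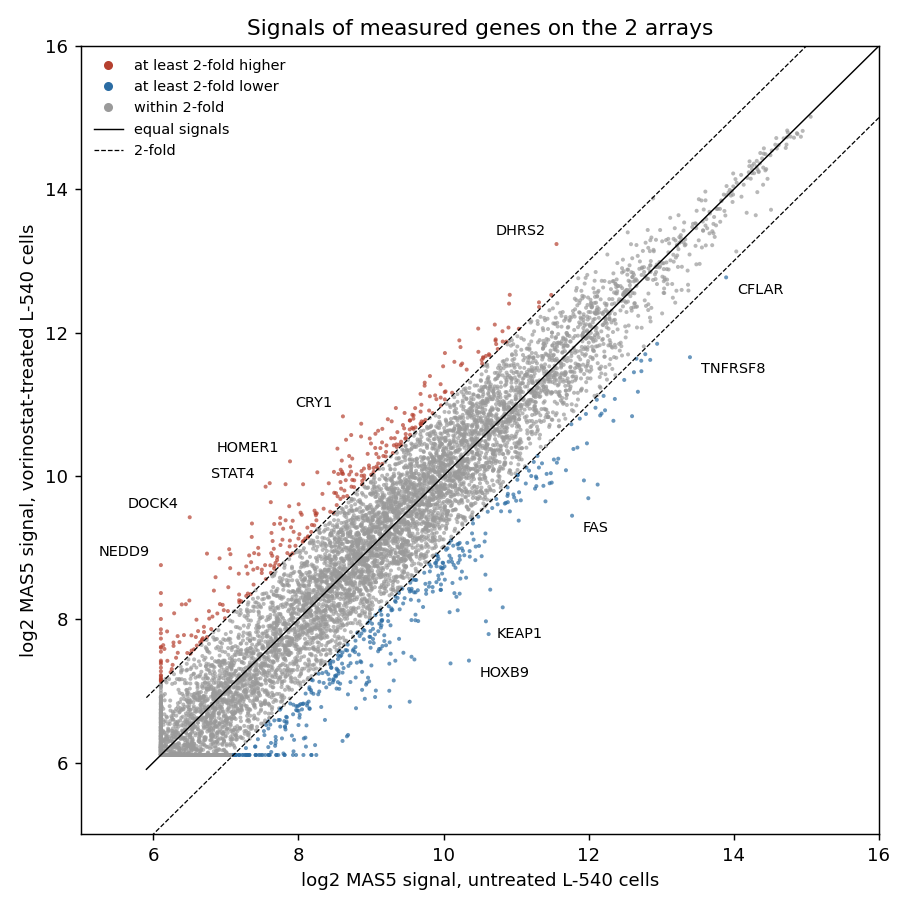
Log2 MAS5 signals of the 8277 measured genes in untreated (x axis) and vorinostat-treated (y axis) L-540 cells, 1 array each, with signals under the floor of 68.9 drawn at the floor. Points outside the dashed 2-fold lines are the 312 genes higher (red) and the 424 genes lower (blue) in the treated array; TNFRSF8 and CFLAR are among the lower genes with high signals and DHRS2 among the higher ones.

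Among genes above the floor on both arrays whose probe sets all went the same way, the largest ratio belonged to DOCK4, an activator of the small GTPase Rac, whose signal was 90.7 in the untreated and 686 in the treated array (7.57-fold higher). The transcription factor gene STAT4 went from 187 to 923 (4.93-fold higher), the synaptic scaffold gene HOMER1 was 4.99-fold higher, the formin gene DAAM1 4.90-fold, the circadian repressor gene CRY1 4.65-fold and RITA1, a regulator of Notch signalling, 4.52-fold. Also higher were the glutaredoxin gene GLRX (4.17-fold), the serpin gene SERPINI1 (4.04-fold), the transcription factor gene MYBL1 (3.93-fold), the fatty acid elongase gene ELOVL4 (3.82-fold), the choline kinase gene CHKA (3.81-fold) and the lysosomal sialidase gene NEU1 (3.64-fold). Among genes at the floor in the untreated array, NEDD9, a docking protein in integrin signalling, was at least 6.27-fold higher, the vesicle GTPase gene RAB3A at least 4.79-fold, ZNF324 at least 4.27-fold, the sulfotransferase gene CHST7 at least 3.73-fold and SURF2 at least 3.37-fold. The second probe set of NEDD9 gave a bound of 1.26 in log2 ratio. HOMER1, DAAM1, CHKA and ZNF324 rest on probe sets that can share sequence with other genes.

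At the other end, HOXB9, a homeobox gene, had signals of 1305 and 172 (7.61-fold lower), on a probe set that can share sequence with other genes. IGHM had 1576 and 222 on its brightest probe set, and its second brightest probe set had a log2 ratio of -1.38. The transcriptional coregulator gene ZMIZ1 was 6.56-fold lower, the noncoding RNA gene FAM30A 6.43-fold, KEAP1, the adaptor that targets NRF2 for degradation, 6.12-fold, and TMED1 5.60-fold. OSBPL10 was 6.28-fold lower on its brightest probe set, which can share sequence with other genes, and its other probe sets were under the floor in the treated array. The signal of FAS was 3495 and 697, and each of its 4 measured probe sets was lower. The interferon regulatory factor gene IRF5 had signals of 4082 and 825 (4.95-fold lower). The adaptor gene DOK2 (4.95-fold), PRDM10 (4.94-fold) and the protein kinase C gene PRKCH (4.92-fold) were lower too. Of genes at the floor in the treated array, AP4M1 was at least 4.41-fold lower, SMYD5 and the adhesion receptor gene ADGRG1 at least 4.21-fold, ZNF710 at least 3.90-fold and NFIC at least 3.64-fold. The second probe set of ZNF710 gave a bound of -0.68 in log2 ratio and that of FAM30A a bound of -1.10. The measured probe sets of FAS and IRF5 and the brightest ones of IGHM and NFIC can share sequence with other genes too.

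For each of 38 fixed gene lists, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of equal size and like signal level. The medians of 4 lists lay above and those of 9 lists below the middle 95% of their random medians. By chance 1.9 of the 38 would lie outside it if genes varied independently of each other. Genes of a list can vary together between any 2 cultures and some genes sit in several lists, so the 1.9 is no yardstick for an effect of treatment. These percentiles describe this pair of arrays and are not a test.

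The list of Hodgkin and Reed-Sternberg cell genes had a median log2 ratio of -0.41 (percentile 0.01), with 8 of its 25 measured members at least 2-fold lower, 0 higher and 17 neither. TNFRSF8 was among the brightest of these, with signals of 10777 and 3228. The AP-1 family genes BATF3 and BATF were 3.40-fold and 2.65-fold lower, and PDGFRA was at least 2.32-fold lower. IRF4 (1.22-fold higher) and GATA3 (1.33-fold higher), further genes typical of these cells, lay within 2-fold. CCL17, a chemokine gene typical of Hodgkin cells, was at or under the floor on both arrays. With the floor at the 60th percentile this list's percentile was 5.23.

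The B cell programme had a median of -0.54 (percentile 0.07), with 5 of 17 measured members lower, 0 higher and 12 neither. Beside IGHM, the Src family kinase gene BLK was 3.77-fold lower, and the transcription factor genes IKZF1 and PAX5 were 2.71-fold and 2.46-fold lower. The other measured probe set of PAX5 was at the floor in the treated array, and the median log2 ratio with that bound was -0.70. T cell and natural killer cell markers had a median of -0.57 (percentile 0.25), with 4 of 15 lower, 0 higher and 11 neither. CD247 had signals of 4463 and 942, the perforin gene PRF1 was 2.40-fold lower, the adaptor gene LAT 2.33-fold and CD3E at least 2.01-fold. This percentile was 15.3 with the floor at the 25th percentile and 33.4 with an offset in place of the floor, settings that also measure dimmer members.

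JAK-STAT and cytokine signalling genes had a median of -0.35 (percentile 0.1), with 5 of 26 lower, 1 higher and 20 neither. The receptor genes IL6R and IL4R were 2.99-fold and 2.63-fold lower and STAT6 had signals of 3541 and 1329, whereas STAT4 was the member that was higher. NF-kB target genes had a median of -0.32 (percentile 0.37), with 6 of 22 lower, 1 higher and 15 neither. The adhesion molecule gene ICAM1 was 2.96-fold lower, STAT5A 2.61-fold and the anti-apoptotic gene BCL2L1 2.47-fold, and the phosphatase gene PTPN1 was 2.87-fold higher. The NF-kB percentile was 4.16 with the offset and 8.1 without shared-sequence probe sets. Interferon response genes had a median of -0.19 (percentile 8.5), with 5 of 29 lower, 1 higher and 23 neither; OAS2 was 2.97-fold, MX2 2.79-fold, IRF7 2.53-fold and IRF9 2.43-fold lower.

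**Figure D2:**
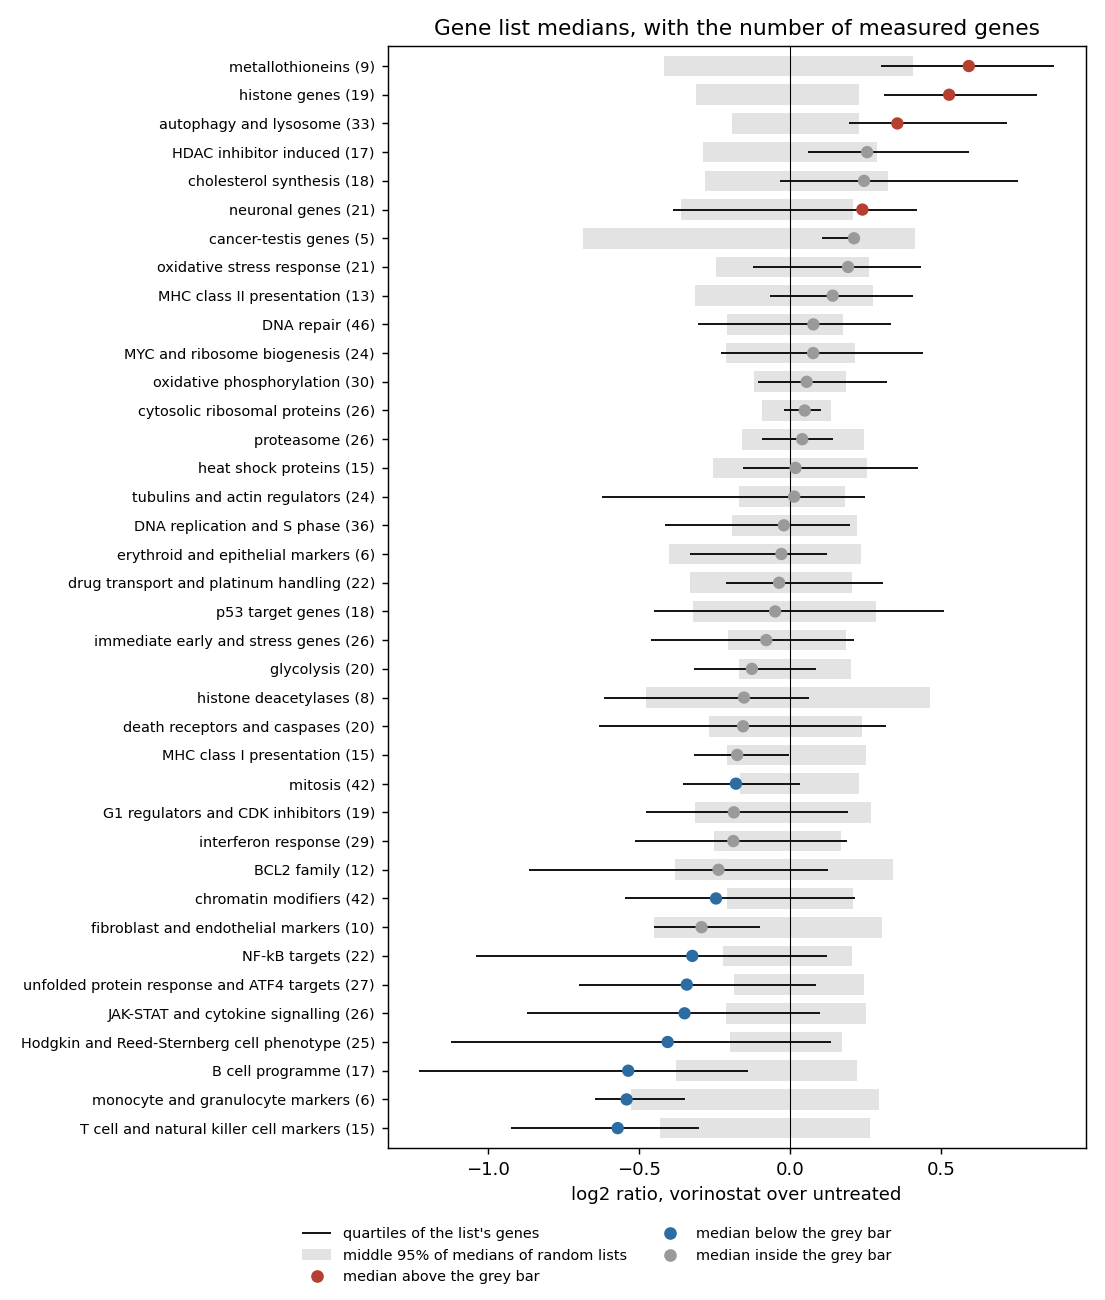
Median log2 ratio (vorinostat over untreated, x axis) of the 38 gene lists, with the number of measured genes in brackets; black lines span the quartiles of the list's genes and grey bars the middle 95% of medians of 10000 random lists of equal size and like signal level. The 4 red medians lie above and the 9 blue medians below the grey bars, with metallothioneins at 0.59 and T cell and natural killer cell markers at -0.57 as the extremes.

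The list of unfolded protein response and ATF4 target genes had a median of -0.34 (percentile 0.11), with 3 of 27 lower, 1 higher and 23 neither. The pseudokinase gene TRIB3 was 3.45-fold lower, CEBPB 3.05-fold and ATF4 itself 2.26-fold. The chaperone gene HSP90B1 was 2.36-fold higher on its brightest probe set, and its probe sets went in different directions. Mitosis genes had a median of -0.18 (percentile 1.77), with 3 of 42 lower, 0 higher and 39 neither. PLK4, which drives centriole duplication, was 2.29-fold lower, the kinase gene AURKA 2.15-fold and the ubiquitin ligase partner gene UBE2C 2.02-fold, and CKS2 was 1.92-fold higher. Without shared-sequence probe sets the mitosis percentile was 11.96 and the log2 ratio of AURKA was -0.46.

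Chromatin modifier genes had a median of -0.25 (percentile 1.15), with 4 of 42 lower, 2 higher and 36 neither. The acetyltransferase genes KAT5 and CREBBP were 3.06-fold and 2.47-fold lower, and the histone chaperone gene ASF1A and the methyltransferase gene EZH2 were 2.13-fold and 2.09-fold higher. This percentile was 20.995 without shared-sequence probe sets and 2.52 for the mean in place of the median. Monocyte and granulocyte markers had a median of -0.54 (percentile 2.12) on 6 measured members, of which 0 passed 2-fold in either direction. ITGAM was 1.69-fold lower on its brightest probe set and FCER1G 1.53-fold lower, and 6 of 11 alternative settings kept the list below its random lists.

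Histone genes had a median of 0.53 (percentile 99.99), with 3 of 19 measured members at least 2-fold higher, 0 lower and 16 neither. H1-10 had signals of 1671 and 4426, H2BC21 was 2.36-fold, H2AC6 2.15-fold and H2AC8 1.93-fold higher. On probe sets without a shared-sequence suffix the percentile was 97.2. The metallothionein list had a median of 0.59 (percentile 99.7), with 1 of 9 higher, 0 lower and 8 neither. Its largest ratios belonged to SLC30A1 and to MTF1, the metal-responsive transcription factor gene (1.84-fold higher), which are not metallothioneins; MT1H and MT2A were 1.83-fold and 1.78-fold higher. The MT1 and MT2A genes rest on probe sets that can share sequence with other genes, and without such probe sets too few members were measured to place the list.

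Autophagy and lysosome genes had a median of 0.36 (percentile 99.8), with 6 of 33 higher, 1 lower and 26 neither. NEU1 had signals of 467 and 1697, the proton pump subunit gene ATP6V0D1 was 2.26-fold higher and MAP1LC3B, which encodes an autophagosome marker, 2.10-fold. Neuronal genes had a median of 0.24 (percentile 98.7), with 1 of 21 higher, 1 lower and 19 neither. RAB3A was the higher member, the synaptotagmin gene SYT1 was 2.12-fold lower, RTN1 was 1.89-fold lower and GPRIN2 1.77-fold higher. This percentile was 97.4 after quantile normalization, 95.3 after loess and 15.6 with the floor at the 60th percentile, and 5 of 12 alternative settings kept the list above its random lists.

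**Figure D3:**
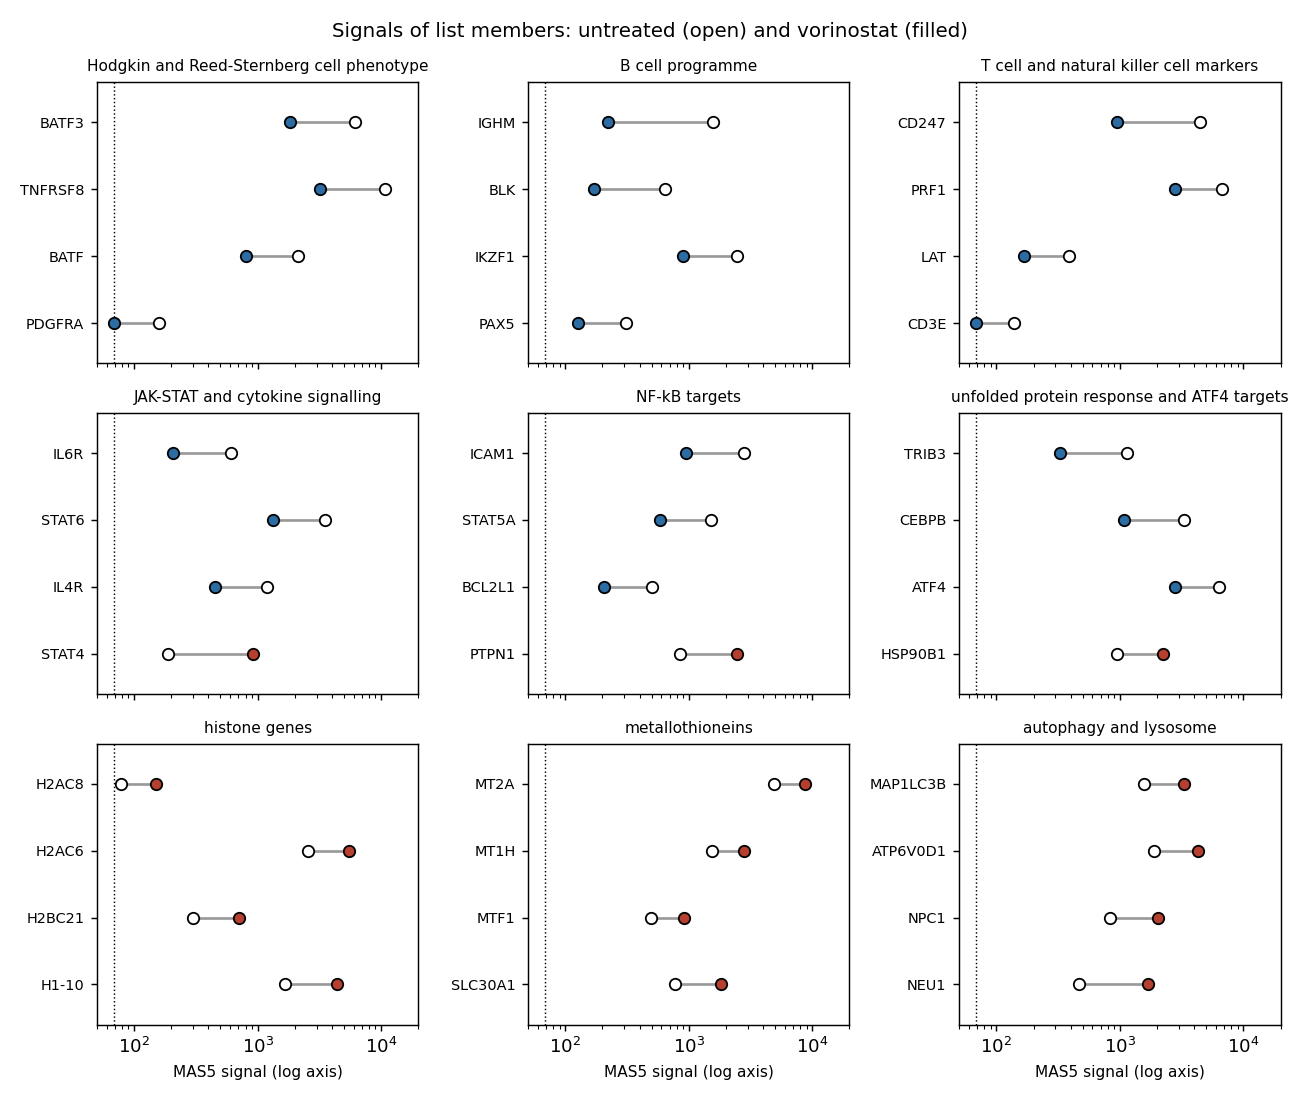
MAS5 signals (log axis) of the 4 members with the largest ratios in each of 9 gene lists, in untreated (open circles) and vorinostat-treated (filled circles) L-540 cells, with the floor of 68.9 as a dotted line. All members drawn for the Hodgkin, B cell and T cell lists were lower in the treated array and all those for the histone, metallothionein and lysosome lists higher, whereas STAT4, PTPN1 and HSP90B1 were higher beside lower members of their lists.

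Genes known to respond to histone deacetylase inhibitors had a median of 0.26 (percentile 96.0, and 99.6 for the mean), with 2 of 17 higher, 0 lower and 15 neither. DHRS2 had signals of 3013 and 9644, and the polyamine acetyltransferase gene SAT1 was 2.88-fold higher. The cell cycle inhibitor gene CDKN1A was 1.55-fold higher (2267 and 3505), TXNIP had a log2 ratio of 0.06, and CCNG2 was 1.73-fold lower on its brightest probe set (a log2 ratio of -0.19 without shared-sequence probe sets). Of the deacetylase genes themselves, 1 of 8 was higher, 2 lower and 5 neither (median -0.15, percentile 26.5). HDAC3 was 2.13-fold higher, HDAC7 3.02-fold lower and HDAC9 at least 2.71-fold lower. HDAC2 was 1.41-fold higher, and HDAC1 and HDAC6 had log2 ratios of -0.09 and -0.08.

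Most genes of cell growth and survival lay within 2-fold, where 91.1% of all measured genes did. The number within 2-fold was 33 of 36 for replication and S phase genes and 18 of 19 for G1 regulators. It was 10 of 12 for the BCL2 family, 16 of 20 for death receptors and caspases and 14 of 18 for p53 targets. In each of these survival lists the share was smaller than among all measured genes. The lists are short, and FAS and BAX each sit in more than 1 of them. DNA replication and S phase genes had a median of -0.02 (percentile 40.3), with 1 of 36 higher and 2 lower: the replication licensing genes CDT1 and MCM5 were 2.76-fold and 2.45-fold lower and CDC6 2.51-fold higher. Of 19 regulators of G1, 1 was higher and 0 lower (median -0.19, percentile 14.3), with CCND3 2.90-fold higher and CCND2 1.17-fold lower on its brightest probe set (median log2 ratio of -0.87 over its probe sets). The BCL2 family had 2 of 12 lower and 0 higher (median -0.24, percentile 10.0, and 2.19 for the mean), namely BAX, which permeabilises mitochondria (3.66-fold), and BCL2L1. BCL2 was 1.38-fold lower on its brightest probe set, with a log2 ratio of -1.12 on its second and a median of -0.64 over its 4 probe sets. MCL1 had a log2 ratio of 0.09 on its brightest probe set and a median of -0.35 over its 5 probe sets. Of 20 death receptor and caspase genes, 3 were lower and 1 higher (median -0.16, percentile 11.98, and 1.57 with the median over probe sets): FAS, the caspase inhibitor gene XIAP (2.55-fold, but a log2 ratio bounded at -0.63 by the floor on its other probe set), and the caspase-8 regulator gene CFLAR (2.18-fold, with each of 11 probe sets lower) against TNFRSF1B (2.24-fold higher). Among 18 p53 target genes, 3 were lower and 1 higher (median -0.05, percentile 40.1), with FAS, BAX and DDB2 (2.54-fold) lower and SAT1 higher. MYC had a log2 ratio of -0.09, and 0 of the 24 MYC and ribosome biogenesis genes passed 2-fold (median 0.08, percentile 77.9), ODC1 being 1.98-fold higher.

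Of 46 DNA repair genes, 0 were higher and 2 lower (median 0.08, percentile 83.6), DDB2 and MSH3 (2.19-fold on its brightest probe set, with its other probe set going the other way); ERCC1 was 1.26-fold lower. Drug transport and platinum handling genes had 1 of 22 higher and 0 lower (median -0.04, percentile 56.8). The glutathione synthesis gene GCLC was 2.01-fold higher on its brightest probe set (median log2 ratio of 0.71 over its probe sets). The copper transporter genes ATP7A and SLC31A1 were 1.68-fold and 1.64-fold higher, and the drug efflux gene ABCB1 was 1.61-fold higher. ABCC1 had a log2 ratio of -0.01 on its brightest probe set and -0.48 on its other one. Oxidative stress genes had 0 of 21 higher and 1 lower, KEAP1 (median 0.19, percentile 91.4), with PGD 1.71-fold and SOD1 1.60-fold higher and TXN at a log2 ratio of 0.32. Cholesterol synthesis genes had 3 of 18 higher and 0 lower (median 0.25, percentile 92.5, and 99.7 for the mean): the synthase gene HMGCS1 (3.53-fold), LSS (2.53-fold, with probe sets in different directions) and SQLE (2.22-fold). The median log2 ratio over probe sets was 0.97 for LSS and 0.64 for SQLE, both short of 2-fold. Glycolysis genes had 1 of 20 higher, PFKFB3 (2.93-fold), and 0 lower (median -0.13, percentile 5.61). Immediate early and stress genes had 2 of 26 higher and 2 lower (median -0.08, percentile 25.6, and 2.3 without shared-sequence probe sets), with SGK1 2.83-fold and DUSP6 2.29-fold higher (median log2 ratio of 0.82 over the probe sets of DUSP6) and FOSL2 2.47-fold and JUNB 2.03-fold lower. Tubulin and actin regulator genes had 1 of 24 higher, VCL (2.30-fold), and 0 lower (median 0.01, percentile 57.1, and 0.59 without shared-sequence probe sets).

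Antigen presentation genes of MHC class I had 0 of 15 higher and 1 lower, the immunoproteasome gene PSMB10 (2.01-fold; median -0.17, percentile 3.66, and 1.76 with the median over probe sets), and 0 of 13 MHC class II genes passed 2-fold (median 0.14, percentile 87.1), HLA-DOB being 1.85-fold higher. No member passed 2-fold among 15 heat shock protein genes (median 0.02, percentile 56.6; BAG3 1.88-fold higher), 26 proteasome genes (median 0.04, percentile 54.3; PSMB5 1.51-fold lower), 30 oxidative phosphorylation genes (median 0.06, percentile 65.9; CYC1 1.74-fold lower), 26 cytosolic ribosomal protein genes (median 0.05, percentile 71.2; RPL27 1.17-fold higher) or 5 cancer-testis genes (median 0.21, percentile 91.8; MAGEA12 1.17-fold higher). Markers of other cell types, beyond the monocyte list above, lay inside the middle 95% of their random medians: of 10 measured fibroblast and endothelial markers 1 was lower, COL6A3 (2.38-fold), and 0 higher (median -0.29, percentile 21.9), and of 6 erythroid and epithelial markers 1 was lower, MUC1 (2.10-fold), and 0 higher (median -0.03, percentile 64.9).

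With 1 array per group, the number of arrays limits the precision and no error across cultures can be given. As a yardstick within this pair of arrays, 2428 pairs of probe sets of the same gene differed in log2 ratio with an SD of 0.42, and all measured probe sets went the same way for 99 of 112 genes called higher and 162 of 173 called lower that had several. Over all 2746 genes with several the share was 71.5%, and the called genes were selected on 1 of those probe sets.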

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

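With 1 array per group there were no replicates, so no paired analysis was possible and no test was run. The median log2 ratio of all genes stayed within 0.1 of 0 under each scaling. Each scaling brings the 2 arrays to a common level, so a shift of all genes could not have been seen. Counts of higher and lower genes were 1051 and 1283 at 1.5-fold, 45 and 77 at 3-fold and 471 and 707 with the offset in place of the floor; they were 459 and 689 with the floor at the 25th percentile, 217 and 251 with it at the 60th, 355 and 391 after quantile normalization and 220 and 251 without shared-sequence probe sets, where 5187 genes were measured. Of 448 list values under alternatives, 419 kept their side of the limits. JAK-STAT (percentiles 0.12 to 0.69), B cell (0 to 0.25), unfolded protein response and ATF4 (0.045 to 0.77), and autophagy and lysosome (99.67 to 100) did so in each of 12 settings, and metallothioneins (99.44 to 99.89) in the 11 that measured enough members, which leave out the one without shared-sequence probe sets. The percentiles that crossed a limit follow by setting; the cause was not tested. With the mean in place of the median they were 99.64 for HDAC inhibitor induced genes, 99.69 for cholesterol synthesis, 2.19 for the BCL2 family, 90.54 for neuronal genes, 5.94 for monocyte and granulocyte markers and 2.52 for chromatin modifiers. Neuronal genes were at 97.4 after quantile normalization, and at 95.28 after loess, where monocyte markers were at 2.85. The floor at the 25th percentile gave neuronal genes 93.99, T and natural killer cell markers 15.295 and monocyte markers 19.13. The floor at the 60th gave the Hodgkin list 5.225 and turned neuronal genes to the lower side, at 15.605. The offset gave NF-kB targets 4.155, T and natural killer cell markers 33.36 and monocyte markers 39.005. The poly-A floor gave HDAC inhibitor induced genes 97.65 and neuronal genes 90.725. The median over probe sets gave MHC class I 1.755, death receptors and caspases 1.57 and monocyte markers 6.55. Without shared-sequence probe sets 1 list stayed above the limits, autophagy and lysosome; histone genes were at 97.225, mitosis at 11.955, NF-kB targets at 8.1, neuronal genes at 85.24, tubulins and actin regulators at 0.59, chromatin modifiers at 20.995 and immediate early genes at 2.3. Of 1596 values of named genes, 86 moved by more than 0.42, the SD between probe sets of a gene. Of these, 35 moved with the floor at the 60th percentile, which by design sets signals under 228 to that value. A further 16 moved with the median over probe sets and 11 without shared-sequence probe sets. The rest were 10 with each of the 2 lower floors, 3 with the offset and 1 after quantile normalization. Signal over background limits the 320 genes at the floor in the untreated and the 584 in the treated array, whose ratios are bounds.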

Other observations

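Of these observations, the gene families were picked out after their values were seen, and the tests of S phase genes and of random lists matched on neighbours were chosen only after the result was seen. A scan covered 93 families of genes sharing the letters that start their symbols, with at least 10 measured genes each. It placed 11 above and 4 below the middle 95% of random lists. By chance 4.65 would lie outside if genes varied independently, which members of a family need not do. Subunits of the vacuolar proton pump, which acidifies lysosomes, stood out within the ATP family: 14 of 15 measured genes had ratios above 1, 4 were at least 2-fold higher, and the median log2 ratio was 0.72 (percentile 100; 99.99 to 100 over 9 other settings). The largest were ATP6V1D (3.06-fold higher), ATP6V1B2 (2.38-fold) and ATP6V0D1 (2.26-fold), and ATP6V0E1 had a log2 ratio of -0.06. Only ATP6V0D1 and ATP6V1H were in the fixed lysosome list. Autophagy genes with ATG symbols had a median of 0.50 (percentile 99.7), with 11 of 13 within 2-fold, ATG2A 2.36-fold and ATG3 2.06-fold higher and ATG13 1.88-fold lower. ATG5, ATG7 and ATG12 were also in the fixed list of autophagy and lysosome genes. Syntaxins, which fuse vesicles, had a median of 0.48 (percentile 99.7, and 90.9 without shared-sequence probe sets), with 13 of 14 within 2-fold, STX7 2.14-fold and STX3 1.98-fold higher. Other families above the middle 95% included FAM (percentile 99.94), ALDH (99.84) and POLR (99.55), so the scan did not single out lysosome and vesicle genes.

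Of 13 lysine demethylase (KDM) genes, 0 passed 2-fold in either direction, but 11 had ratios below 1, with a median of -0.55 (percentile 0.33; 23.7 without shared-sequence probe sets). KDM4A was 1.96-fold and KDM4B 1.67-fold lower, and KDM1A was 1.42-fold higher. KDM1A, KDM4A, KDM5A, KDM6A and KDM6B were also in the fixed list of chromatin modifiers. Collagen genes had a median of -0.31 (percentile 1.89), with COL6A3 and COL4A3 2.38-fold and 2.36-fold lower, the other 18 within 2-fold and 17 of all 20 below 1; over other settings the percentile ranged from 0.35 to 6.58.

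The list of histone genes had a median log2 ratio of 0.53, with 3 of 19 measured members at least 2-fold higher, 16 within 2-fold and 3 below a ratio of 1. A trend of the ratio with signal level is argued against as the whole cause, since after loess the median was still 0.53. The percentile after loess, 100, adds little, since the random lists were already matched on level. Signal shared between near-identical histone genes stays open: H1-10, H2BC21 and H2AC6, the members past 2-fold, rest on probe sets with a shared-sequence suffix, and on probe sets without a shared-sequence suffix the median was 0.37 over 9 genes and the percentile 97.225. A larger share of cells in S phase, when many histone genes are transcribed, stays open too. The S phase list showed no rise, with a median of -0.02 at percentile 40.3. The upper end of its bootstrap interval over genes (-0.19 to 0.16) lay under the histone median of 0.53. A smaller rise within that interval was not excluded. A direct effect of the inhibitor may also account for the higher histone genes and was not tested.

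The Hodgkin, B cell and T cell lists together held 56 measured genes with a median log2 ratio of -0.54, 17 at least 2-fold lower and 0 higher. Position in gene-dense neighbourhoods and a trend of the ratio with signal level are argued against as the whole cause. Random lists matched on level and on protein-coding neighbours had a median of -0.05, against -0.51 for the pooled genes. In the tenth of genes with the most neighbours (62 to 112) the median was -0.14. Gene density thus went with a smaller shift than that of the pooled genes. The percentile among the matched lists, 0, adds little. The pooled list was not among the fixed lists. Its Hodgkin, B cell and T cell parts were already at percentiles 0.01, 0.07 and 0.25. After loess the median was -0.46, against -0.54 before. The percentile after loess, 0, adds little, since the random lists were already matched on level. Of the other cell types, monocyte and granulocyte markers were low too (median -0.54, percentile 2.12, 5 of 6 below 1), while fibroblast and endothelial markers (-0.29, percentile 21.9, 9 of 10 below 1) and erythroid and epithelial markers (-0.03, percentile 64.9, 3 of 6 below 1) lay inside their random lists. With the floor at the 25th percentile and with the offset, the T cell list was at percentiles 15.3 and 33.4 and the monocyte list at 19.13 and 39.0. An effect of the inhibitor may explain the pattern, as a hypothesis found and tested on the same pair of arrays, but one specific to lymphoid genes was not shown, and a difference between the cultures unrelated to treatment stays open with 1 array per group.

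Ratios were lower for genes with many protein-coding neighbours within 1 Mb on each side. Across 8098 genes, which are not independent replicates, Spearman's rho was -0.139 (95% interval over chromosomes -0.169 to -0.102); in the tenth of genes with 0 to 8 neighbours 4.94% were at least 2-fold higher and 5.06% lower, against 2.35% and 7.16% in the tenth with 62 to 112. The correlation was weakest, -0.103 (-0.135 to -0.068), with the offset in place of the floor, across 11554 genes, and was -0.136 (-0.164 to -0.101) after quantile normalization. It was -0.135 (-0.162 to -0.099) after loess on signal level, -0.127 (-0.170 to -0.075) without shared-sequence probe sets and -0.141 (-0.172 to -0.103) without genes next to a member of their family. These values argue against a signal level trend, shared signal and clusters of related genes as the whole cause. GC content, which goes with gene density and could act through hybridisation, was not tested and stays open beside a biological effect of chromosomal position.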
